A study of Mus musculus with 8 samples.

How the data were processed

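The data are 3′-end RNA sequencing libraries from mouse dorsal root ganglia, the clusters of sensory neuron cell bodies and their glia beside the spinal cord. One sciatic nerve of each mouse was crushed, and lumbar ganglia of levels L4 to L6 were taken 24 h later. The injury group holds ganglia of the crushed side and the naive group holds ganglia of the opposite side, with 4 libraries in each. Per the labels, each repeat pooled ganglia of 2 mice, total RNA was purified with RNeasy Mini columns, and libraries were made with the QuantSeq 3′ mRNA kit in its REV form. That kit primes on the poly(A) tail and reads the transcript end, so that transcript length has little part in the count. Priming on internal stretches of A, or a transcript end that lies outside the annotated gene, can raise or lower a gene's count. The labels call the tissue dissociated ganglia; they do not say whether cells were cultured.

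The deposited table holds whole-number counts per gene symbol, not normalised, with 1 value per gene and library. Per the submitters' processing notes, bcl2fastq 2.17, STAR and HTSeq were used with the builds GRCm38 and mm10, which name the same assembly; versions of STAR and HTSeq, the annotation and the strand setting are not given in the sources used here. Since the table has 1 value per gene, the use of alternative poly(A) sites within a gene, which the series title names, could not be tested. The table has 24060 rows. In 27 of them the symbol had been turned into a calendar date; these rows name no gene, held 0.146% to 0.158% of each library's counts, and were left out of library sizes and tests. Of the other 24033 symbols, 6722 had no count in any library. Rn45s, a ribosomal RNA precursor, held 4.47% to 6.74% of the counts and was kept.

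Library totals ranged from 15446931 to 29412510 counts. Levels are given as CPM, counts scaled to a common library size. A count of 0 in a library allows, at 3 counts, a level of up to 0.102 to 0.195 CPM before TMM scaling. Kpna2, an importin that most cells use, was listed at 0 in all libraries, so a 0 here can come from the counting. Such limits cover counting error only, since reads without molecular identifiers are not independent molecules. No pair of libraries within a group agreed within sampling noise: chi-square per degree of freedom was 8.09 to 19.2 over genes with at least 20 counts in the pair.

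Gene tests used edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr, libraries were scaled by TMM, and the robust quasi-likelihood F-test compared injury with naive in 8 libraries without a block. Adjusted p-values are Benjamini-Hochberg values over the 13639 genes tested, and a gene was called changed at an adjusted p under 0.05. CPM values are TMM-scaled and given as mean ± SD over 4 libraries. Log2 fold changes are injury minus naive, with a standard error. That error was not estimated directly but derived as the absolute log2 fold change divided by the square root of F. It is approximate, above all for genes with few counts in a group. The biological coefficient of variation was 17.1%. Gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the 27 of 29 lists that had at least 3 tested members. Each list's calls are also given adjusted over the list alone, and camera with an estimated correlation is given where it ends a call. Symbols were used as the table gives them, and 1 list member was found under an older symbol through RefSeq synonyms. Positions are those of GENCODE M21 on GRCm38, the build the processing notes name; 13051 tested symbols, 95.7%, matched a single GENCODE gene.

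The design, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. The rule takes 7 fixed genes (Atf3, Jun, Sox11, Sprr1a, Gap43, Gal and Npy). It adds the 12 largest rises and 12 largest falls among called genes with a mean of at least 5 CPM and no overlap between groups, passing over symbols made of Gm and digits or ending in Rik. From each list it takes up to 4 members with the smallest p. The genes Nrn1, Cacna1b, Pecam1, Gfra2, Ntrk2, Nr4a2, Mvd, Mdm2, Bcl2, Bid, Ddit4 and Ncl fall outside the rule; they belong to short counts, with the replicate block included, or stand against their list's direction, and were chosen after their values were seen. Ctss was likewise chosen as the most abundant macrophage marker, and Xist for its counts in 1 library. Some genes that the rule or a short count would take are not reported here.

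Alternatives were a replicate block, DESeq2 size factors or library totals in place of TMM, no low-count filter, a mean of at least 5 CPM, DESeq2 1.42.0, limma-voom, leaving out each library, and, for lists, an estimated correlation and fry. Camera compares a list with the other genes, while fry asks whether the list's genes move, on balance, one way, so a fry p answers another question. A fit without both libraries of number 1 was added after the data were seen. The design text places both sides of the same mice in each repeat, and the numbers in the sample titles were taken to mark these repeats, so the numbers pair the samples. In a check of the deviations from group means, same-numbered libraries correlated at 0.0352 to 0.0569 and others at -0.084 to 0.0378, and 7 of 8 libraries were closest to their own number. The paired model has 3 residual degrees of freedom against 6. The design text gives 2 mice per repeat but does not say outright that repeats used different mice, so p-values measure the spread between these pooled samples.

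The gene test was tested on counts simulated from the real means and library sizes, with the dispersion trend that edgeR fitted over genes. For injury minus naive, over 13465 genes it recovered 72 of 100 genes changed by 1 on the log2 scale and 95 of 98 changed by 2, and 10 of 177 calls were false. The simulation held no pairs, no deviating library and no gene more variable than the trend, so these rates need not hold for the real data. All 35 divisions of the 8 libraries into 4 and 4 were also fitted.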

Results

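Gene expression was measured in lumbar dorsal root ganglia of mice 24 h after a sciatic nerve crush, in 4 libraries of the injured side and 4 of the uninjured opposite side, here called naive. The comparison asks which transcripts change in the ganglion within a day of an injury to the peripheral axons. Total counts were 15446931, 21644254, 22144532 and 29412510 in naive replicates 1 to 4 and 22466009, 21907924, 20047302 and 17141116 in injury replicates 1 to 4. The first principal component of log2 CPM held 31.0% of the variance and parted the groups. The second held 16.6%, with naive replicate 1 at 46.6 and the other libraries between -21.1 and 11.3.

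Transcription factors and growth-associated genes of the axotomy response were higher on the injured side. Atf3, a stress-induced transcription factor (chromosome 1, 191170296 to 191218039 on GRCm38), rose from 58.8 ± 11.7 to 321 ± 34.2 CPM (SD, n = 4), 5.47-fold. Sox11 (chromosome 12, 27334264 to 27342574), a SRY-box factor, rose from 49.6 ± 1.47 to 353 ± 61.6 CPM, and Jun (chromosome 4, 95049034 to 95052222), a component of AP-1, rose from 450 ± 29.1 to 811 ± 53.1 CPM. Their log2 fold changes were 2.45 ± 0.13 (SE), 2.83 ± 0.11 and 0.85 ± 0.06, with edgeR adjusted p of 3.36e-07, 8.98e-11 and 2.03e-10. Sprr1a (chromosome 3, 92483952 to 92485895), a small proline-rich protein, rose from 0.345 ± 0.118 to 33.1 ± 14.01 CPM (log2 fold change 6.56 ± 0.45, adjusted p = 2.87e-06). Gap43 (chromosome 16, 42248442 to 42340651), a growth cone protein that was already abundant, rose 1.39-fold, from 363 ± 24.7 to 505 ± 74.4 CPM (adjusted p = 0.00116).

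The neuropeptide genes Gal (chromosome 19, 3409915 to 3414544) and Npy (chromosome 6, 49822710 to 49829507) rose from 40.6 ± 4.27 to 175 ± 64.7 CPM and from 0.716 ± 0.727 to 23.5 ± 9.21 CPM. Log2 fold changes were 2.10 ± 0.34 and 5.18 ± 0.85, with adjusted p of 0.00916 and 0.00965. All 4 injury libraries lay above all naive ones for both genes, but injury replicate 1 stood at 78.9 and 9.87 CPM against at least 192 and 26.9 CPM in the others. With the replicate block neither passed the threshold (adjusted p = 0.0750 and 0.0807); over all alternatives the adjusted p ranged from 8.82e-17 to 0.0750 for Gal and from 0.000165 to 0.0807 for Npy.

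**Figure D1:**
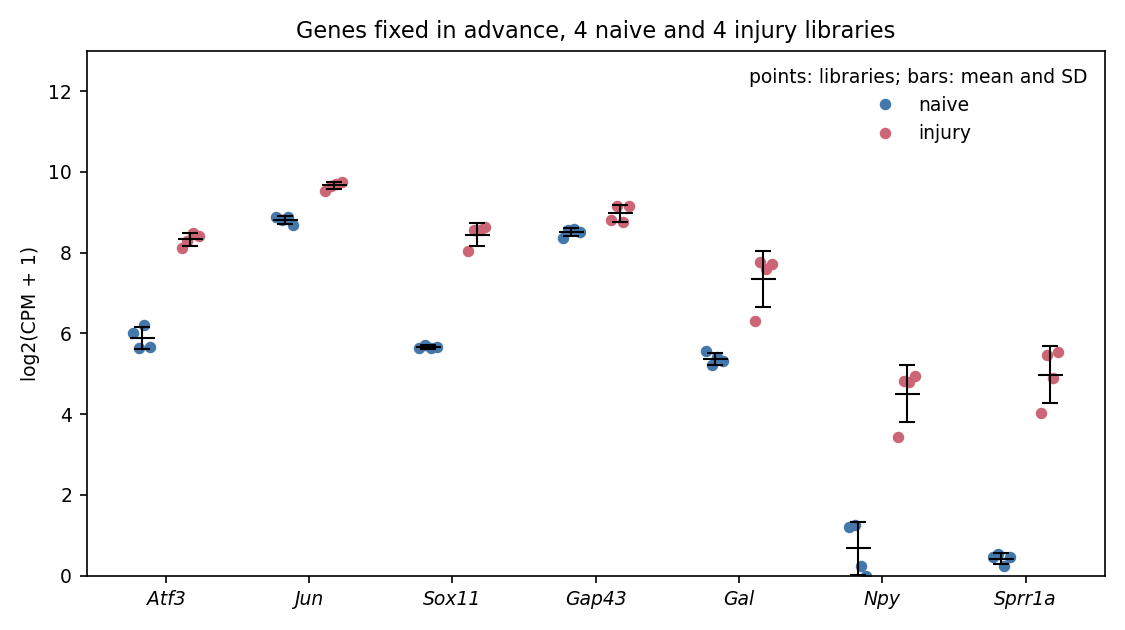
Expression of the 7 genes fixed in advance. The vertical axis is log2(CPM + 1); each point is a library, and bars are the mean and SD of 4 naive or 4 injury libraries. All injury libraries lie above all naive libraries for each gene, and injury replicate 1 is the lowest injury library for Atf3, Jun, Sox11, Gal, Npy and Sprr1a.

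Of 13639 genes tested, 1717 changed: 1108 were genes higher after injury and 609 were genes lower after injury. Changes of at least 2-fold were mostly rises, 240 against 29, and among genes with a mean of at least 5 CPM they were 169 against 9. The median called rise was 1.45-fold and the median called fall 1.35-fold. The groups did not overlap in 2295 tested genes, 16.8%, where chance gives 2.86%. Scaling by library totals gave another balance, 889 higher and 1001 lower, 47.0% higher, and moved the median log2 fold change of all genes from -0.004 to -0.06.

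The largest rises under the naming rule, after Sprr1a, included the following. Lce1g, of the late cornified envelope family, rose from 9 counts in all naive libraries together to 802 in the injury libraries (log2 fold change 6.55 ± 0.50), a value that is uncertain where its reads are shared with near-identical family members. Timp1, an inhibitor of metalloproteinases, rose from 0.563 ± 0.368 to 17.1 ± 5.03 CPM, and Areg, the epidermal growth factor receptor ligand amphiregulin, from 0.456 ± 0.165 to 14.7 ± 1.40 CPM. Tmem88b, a transmembrane protein, rose from 2.33 ± 1.47 to 63.3 ± 19.0 CPM and Procr, the protein C receptor, from 6.64 ± 1.53 to 93.8 ± 19.2 CPM. Star, which carries cholesterol into mitochondria, rose 16.9-fold, Fst, an activin-binding protein, 10.8-fold, Aim2, a cytosolic DNA sensor, 11.8-fold and Gadd45a, a growth arrest and DNA damage gene, 10.2-fold. For these 9 genes the adjusted p ranged from 5.11e-12 (Areg) to 0.000446 (Tmem88b). Timp1 and Aim2 overlap Syn1 and Cadm3 on the opposite strand, whose own log2 fold changes were -0.02 and 0.15; as the strand setting of the counting is not given, counts of such pairs are uncertain.

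Under the naming rule, which asks for a mean of at least 5 CPM and no overlap between groups, the falls were smaller. Oprl1, the nociceptin receptor, fell from 17.8 ± 2.78 to 7.46 ± 0.251 CPM (log2 fold change -1.26 ± 0.16, adjusted p = 5.23e-06). Sstr1, a somatostatin receptor, fell from 7.64 ± 1.30 to 3.30 ± 1.44 CPM, Adora2a, an adenosine receptor, from 10.5 ± 1.42 to 4.91 ± 1.27 CPM and Chrm2, a muscarinic acetylcholine receptor, from 11.6 ± 3.18 to 5.61 ± 1.32 CPM. Chrna6, a nicotinic receptor subunit, fell from 34.8 ± 5.55 to 15.9 ± 6.24 CPM (adjusted p = 0.0160); the call was lost without injury replicate 2 (0.0538) and with no low-count filter (0.0551). The kinases Camk1g and Dapk2 had log2 fold changes of -1.04 and -0.98, the transcription factor Scx -0.98, the netrin receptor Unc5b -0.95, the cadherin Cdh10 -0.94, Islr2 -0.98 and Fam196b -0.96. Adjusted p for these 12 falls ranged from 1.16e-06 (Camk1g) to 0.0160 (Chrna6). Scx and Fam196b overlap Bop1 and Dock2 on the opposite strand and Islr2 overlaps Islr on its own, so these counts are uncertain in the same way.

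**Figure D2:**
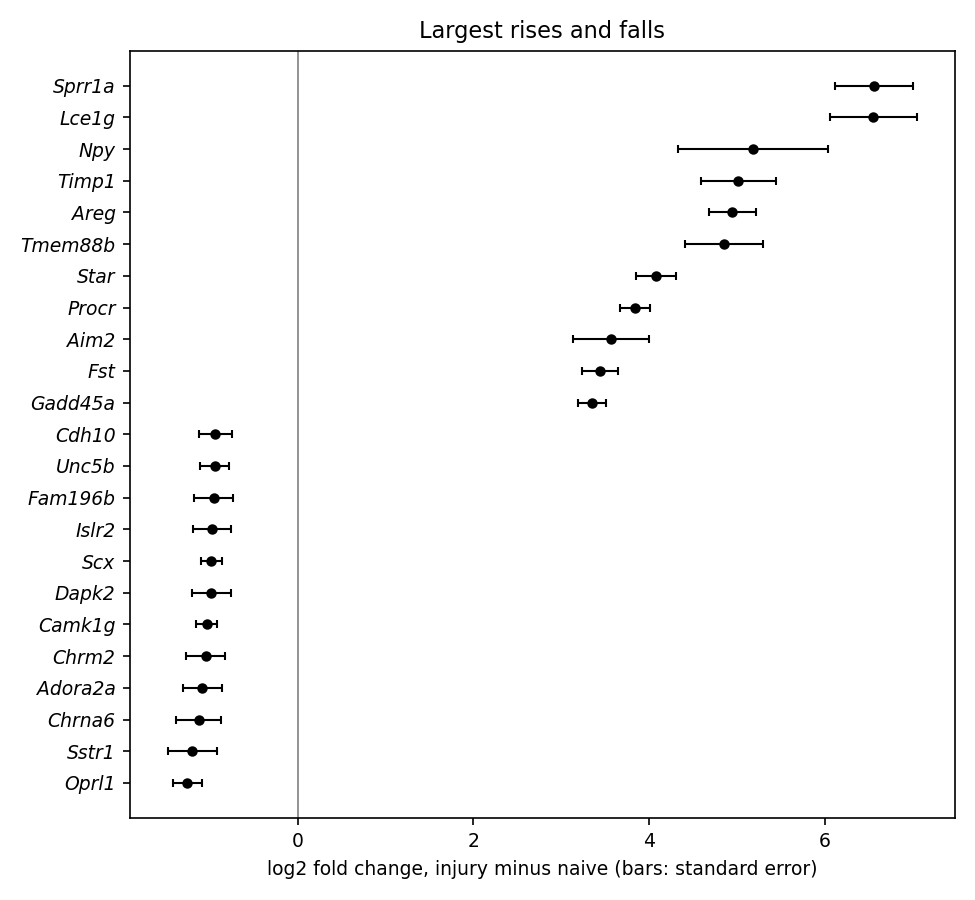
The largest rises and falls under the naming rule, for the genes named in the text. The horizontal axis is the log2 fold change, injury minus naive, and bars are its standard error, derived from the F statistic, with 4 libraries per group. Rises reach 6.56 (Sprr1a), while the deepest fall is -1.26 (Oprl1).

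Among 23 injury-induced transcription factors, 18 rose and 1 fell (19 and 1 adjusted over the list alone), with a median log2 fold change of 0.47. Besides Sox11, Jun and Atf3, Klf6, a Krüppel-like factor, rose from 156 ± 5.21 to 360 ± 56.6 CPM and Smad1, a mediator of bone morphogenetic protein signals, from 64.7 ± 4.82 to 117 ± 10.4 CPM. Egr1, an immediate early gene, was the member that fell, from 380 ± 35.2 to 320 ± 31.0 CPM (adjusted p = 0.0223), but not without naive replicate 1 or 3 or injury replicate 2 or 4 (0.0592 to 0.101). Of 31 regeneration-associated effectors, 27 rose and 1 fell (28 and 1 adjusted over the list alone), with a median of 1.74. The neurotrophin gene Bdnf rose from 101 ± 5.23 to 321 ± 41.5 CPM, the semaphorin Sema6a from 15.6 ± 2.63 to 144 ± 21.9 CPM, the laminin receptor subunit Itga7 from 83.4 ± 4.76 to 279 ± 40.1 CPM and the neuropeptide gene Nts from 8.37 ± 1.75 to 32.2 ± 2.93 CPM. Nrn1, the neurite outgrowth protein neuritin, fell from 562 ± 13.2 to 419 ± 20.6 CPM. Camera adjusted p was 1.10e-11 for the factors and 8.88e-27 for the effectors; with an estimated correlation the factors stayed past the threshold (adjusted p = 0.0451, but adjusted p = 0.396 with an estimated correlation and the replicate block) and the effectors did not (adjusted p = 0.0642). Both lists were written from genes known to respond to axon injury.

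Of 19 genes of the unfolded protein and integrated stress response, 8 rose and 1 fell (9 and 1 adjusted over the list alone; camera adjusted p = 9.86e-05, and adjusted p = 0.0642 with an estimated correlation). Chac1, which degrades glutathione, rose from 12.5 ± 2.29 to 34.1 ± 2.60 CPM; the transcription factor genes Ddit3 and Atf4 rose 1.38-fold and 1.43-fold, and the chaperone gene Hspa5 1.30-fold. Ddit4, an inhibitor of mTORC1, fell from 101 ± 14.01 to 73.5 ± 12.9 CPM. Among 15 cell death and p53 target genes, 5 rose and 2 fell, with the same numbers adjusted over the list alone. Among those that rose, Cdkn1a, the cell cycle inhibitor p21, increased from 82.8 ± 10.03 to 264 ± 25.5 CPM, the TWEAK receptor gene Tnfrsf12a from 2.51 ± 0.356 to 14.98 ± 4.39 CPM and the BH3-only gene Pmaip1 from 2.49 ± 0.928 to 10.1 ± 2.36 CPM, and Mdm2 rose 1.28-fold. The members that fell were Bcl2, which restrains apoptosis (1.25-fold lower), and Bid, which promotes it (1.29-fold lower). Bid was not called without naive replicate 1 or 3 or injury replicate 2 (adjusted p 0.0538 to 0.0773) or both libraries of number 1 (0.113). The list missed the threshold (camera adjusted p = 0.0638) but passed it without naive replicate 4 (0.0415) or injury replicate 3 (0.0329), with a mean of at least 5 CPM (0.0495) and with limma-voom (0.0481). Fry, which tests for a shift of the list without comparing it with other genes, gave 0.00848, and the range over all alternatives was 0.00848 to 0.547, the latter the adjusted p with an estimated correlation.

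Several cytokine and interferon pathway genes were also higher. Of 15 cytokine receptor and JAK-STAT feedback genes, 7 rose and none fell, the same 7 and 0 adjusted over the list alone (camera adjusted p = 0.00241, and adjusted p = 0.0642 with an estimated correlation). The feedback inhibitor Cish rose from 16.4 ± 1.60 to 37.5 ± 6.70 CPM and Socs2 from 54.1 ± 4.69 to 91.0 ± 14.8 CPM, Stat3 from 510 ± 20.5 to 684 ± 22.0 CPM and the kinase gene Jak2 from 15.9 ± 2.29 to 24.4 ± 2.33 CPM. Of 14 interferon-stimulated genes, 9 rose and 0 fell (11 and 0 adjusted over the list alone), with a median of 0.83 (camera adjusted p = 2.02e-05, and adjusted p = 0.484 with an estimated correlation). Ifit1, an antiviral RNA-binding protein, rose from 22.2 ± 2.27 to 81.4 ± 27.9 CPM, the protease gene Usp18 from 2.44 ± 0.936 to 8.65 ± 3.90 CPM, Oasl2 from 15.5 ± 1.88 to 28.0 ± 7.63 CPM and Stat2, a component of the interferon-activated transcription complex, from 18.7 ± 1.33 to 32.9 ± 0.202 CPM. The summed interferon-stimulated genes were 387 CPM in injury replicate 1 and 541 to 601 CPM in the other injury libraries, against 324 to 391 CPM in the naive ones.

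Genes of neuronal signalling changed in both directions. Of 32 sensory neuron ion channels, 2 rose and 6 fell (3 and 8 adjusted over the list alone). Cacna1b, an N-type calcium channel, was among those that rose, 1.19-fold, but was not called without injury replicate 4 (adjusted p = 0.0677). Among those that fell, the potassium channel gene Kcna2 went from 284 ± 19.5 to 226 ± 10.1 CPM, and another, Kcns3, was 1.44-fold lower. Camera gave an adjusted p of 0.0587 for the channels, 0.0497 with the replicate block, and 0.0156, 0.0357 and 0.0356 without naive replicate 1, injury replicate 2 and injury replicate 3. It was 0.0325 with no low-count filter, 0.0450 with a mean of at least 5 CPM, 0.0203 with limma-voom and 0.0401 without both libraries of number 1; the range over all alternatives was 0.0156 to 0.547. With an estimated correlation the adjusted p was 0.547, and 0.551 with an estimated correlation and the replicate block. Trpv1, the capsaicin receptor, was listed at 0 in all libraries. Of 14 opioid, GABA and other inhibitory receptors, 1 rose and 4 fell, with the same numbers adjusted over the list alone (camera adjusted p = 0.0638). Fry, which does not compare the list with other genes, gave 0.000431, and the range over all alternatives reached an adjusted p of 0.267 with an estimated correlation. The neuropeptide Y receptor gene Npy1r rose from 21.7 ± 2.86 to 38.9 ± 5.01 CPM. Among those that fell were Oprl1, Chrna6 and the metabotropic glutamate receptor gene Grm4 (1.40-fold). Chrna6 was in the list as fixed, but it encodes a subunit of nicotinic receptors, which are excitatory channels. Its fall is therefore not that of an inhibitory receptor, though the list's counts and tests include it. The call of Chrna6 was lost without injury replicate 2 (adjusted p = 0.0538) and with no low-count filter (0.0551).

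Among 22 sensory neuron subtype markers, 3 rose and 3 fell (4 and 8 adjusted over the list alone, 3 and 6 with the replicate block, 3 and 5 with DESeq2 or limma-voom; camera adjusted p = 0.348). The receptor tyrosine kinase gene Ret rose from 346 ± 17.3 to 459 ± 32.9 CPM, Spp1 (osteopontin) from 55.9 ± 11.02 to 90.4 ± 7.71 CPM and the interleukin receptor gene Il31ra from 12.2 ± 1.81 to 20.7 ± 1.52 CPM. Tac1, the substance P precursor, fell from 546 ± 42.3 to 437 ± 15.7 CPM, the neurturin receptor gene Gfra2 from 209 ± 31.1 to 133 ± 22.0 CPM and Ntrk2, the BDNF receptor, from 191 ± 11.7 to 160 ± 13.7 CPM, the last not without naive replicate 2 (adjusted p = 0.0679). Of 19 pan-neuronal and cytoskeletal genes, 2 rose and 1 fell (3 and 2 adjusted over the list alone, 4 and 1 with the replicate block, 3 and 2 with DESeq2, 2 and 2 with limma-voom; camera adjusted p = 0.906). The microtubule-associated protein gene Map1b and the vesicular glutamate transporter gene Slc17a6 rose 1.19-fold and 1.16-fold, and the transcription factor Isl1 fell 1.30-fold. Slc17a6 missed the threshold without injury replicate 2 (adjusted p = 0.0589) and with library totals (0.0546).

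Of 13 satellite glial markers, edgeR called 1 in both adjustments, Glul, glutamine synthetase, rising from 290 ± 16.4 to 408 ± 7.60 CPM (adjusted p = 6.37e-07; list camera adjusted p = 0.567); DESeq2 called 1 higher, limma-voom 1 higher and 1 lower. Fabp7, a fatty acid binding protein of these glia, had 241 ± 30.3 and 180 ± 35.8 CPM (adjusted p = 0.0912), and was called lower with the replicate block (8.84e-05), library totals (0.0324) and limma-voom (0.00613), without naive replicate 2 (0.0234) and without injury replicate 3 (0.000105), with a range of 8.84e-05 to 0.260 over all alternatives. The block also called Lgi4 higher (13.5 ± 2.172 and 18.3 ± 3.88 CPM, adjusted p = 0.0750, 0.0461 with the block), as did leaving out naive replicate 1 (0.0304), with a range of 0.0304 to 0.282. Of 14 myelinating Schwann cell markers, 1 was called in both adjustments, Gldn (gliomedin), from 4.93 ± 1.00 to 9.03 ± 2.00 CPM (adjusted p = 0.00983; 0.0699 without injury replicate 2; list camera adjusted p = 0.268). None of 17 macrophage markers passed edgeR's test, over all genes or adjusted over the list alone (list camera adjusted p = 0.858); 3 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. Those 3 were Cd14 (2.168 ± 0.538 and 3.99 ± 1.43 CPM), Mrc1 (2.35 ± 0.986 and 3.96 ± 0.965 CPM) and Cx3cr1 (1.16 ± 0.796 and 2.55 ± 1.14 CPM). None of 10 neutrophil markers and none of 15 endothelial and mural markers passed edgeR's test in either adjustment (camera adjusted p = 0.906 and 0.702), with 0 and 1 at an unadjusted p under 0.05 and 0 called by DESeq2 or limma-voom. The replicate block called 1 endothelial marker higher, Pecam1, with 39.4 ± 11.6 and 50.7 ± 21.6 CPM (adjusted p = 0.593, 0.0316 with the block, range 0.0316 to 0.931 over all alternatives). Of 12 antigen presentation genes, 2 rose (5 adjusted over the list alone, 1 with limma-voom; camera adjusted p = 0.270): the immunoproteasome subunit Psmb8, from 13.5 ± 3.53 to 20.9 ± 1.20 CPM, and the peptide transporter Tap1, from 9.04 ± 2.49 to 14.1 ± 3.60 CPM. Tap1 (adjusted p = 0.0463) was not called without naive replicate 1, 2 or 3 or injury replicate 2 or 4 (0.108 to 0.207), with library totals (0.0639) or with limma-voom (0.0908). Of 11 fibroblast markers, 1 rose in both adjustments, Pdgfra, from 1.60 ± 0.377 to 3.61 ± 0.362 CPM (adjusted p = 0.0287; list camera adjusted p = 0.923), but not without naive replicate 2 or 3 or injury replicate 2, 3 or 4 (0.0595 to 0.0750).

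Of 20 genes of cholesterol synthesis and uptake, 5 rose and none fell, also adjusted over the list alone, with a median of 0.15. Among them were Hsd17b7 (1.68-fold) and Sqle (1.30-fold), both enzymes of sterol synthesis, and Idi1 (1.38-fold) and Mvd (1.23-fold), of isoprenoid synthesis. Mvd was not called without naive replicate 2 or injury replicate 3 (adjusted p = 0.0647 and 0.0507). The list's camera adjusted p was 0.0420, and its adjusted p was 0.563 with an estimated correlation; it was 0.109, 0.0581, 0.152 and 0.0595 without naive replicates 1 and 2 and injury replicates 3 and 4. It was 0.0601 with library totals, 0.0651 with a mean of at least 5 CPM and 0.0688 with fry, a test without other genes, and ranged from 0.0127 to 0.563 over all alternatives. Of 16 immediate early genes, 3 rose and 2 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.922): Ier3, Dusp1 and Arc rose 1.32-fold, 1.28-fold and 1.81-fold, and Egr1 and Nr4a2 fell 1.19-fold and 1.47-fold. Nr4a2 was not called without naive replicate 1 or 4 or injury replicate 1, 2 or 4 (adjusted p 0.0745 to 0.119), or both libraries of number 1 (0.172), nor Egr1 without naive replicate 1 or 3 or injury replicate 2 or 4 (0.0592 to 0.101).

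The series addresses poly(A) site choice, so genes of 3′-end formation and RNA binding were listed as well. Of 24 genes of the cleavage and polyadenylation machinery, 1 rose in edgeR's test (4 rose and 1 fell adjusted over the list alone, 3 and 0 with the replicate block, 3 and 1 with DESeq2, 1 and 0 with limma-voom; camera adjusted p = 0.168). It was the poly(A)-binding protein gene Pabpc1, from 185 ± 8.20 to 235 ± 37.5 CPM (adjusted p = 0.0151), which was not called without naive replicate 3 or 4 or injury replicate 2 or 4 (0.0525 to 0.0619) or both libraries of number 1 (0.0725), or with library totals (0.0519). Papola, a poly(A) polymerase, had 84.8 ± 1.97 and 100.2 ± 11.99 CPM (adjusted p = 0.0538), with 0.0417 under the replicate block, 0.0456 with DESeq2, 0.0491 with no low-count filter, 0.00782 without injury replicate 1 and 0.00877 without both libraries of number 1, and a range of 0.00782 to 0.251 over all alternatives. Of 29 RNA-binding proteins of 3′ untranslated regions and axonal mRNA, 5 rose and none fell, also adjusted over the list alone (camera adjusted p = 0.223). Elavl3, a neuronal Hu protein, rose 1.26-fold, from 457 ± 27.9 to 578 ± 78.6 CPM. The splicing factors Srsf3 and Srsf7 rose 1.22-fold each, Igf2bp2, an mRNA-binding protein, 1.93-fold and Ncl, nucleolin, 1.12-fold. Leaving out 1 library ended the call of Srsf3 (injury replicate 2 or 4, adjusted p 0.0523 and 0.0542) and of Igf2bp2 (naive replicate 2 or 3, injury replicate 2 or 3, 0.0511 to 0.0576). The same held for Srsf7 (each library but injury replicate 1, 0.0647 to 0.190) and Ncl (each but naive replicate 1, 0.0523 to 0.210). Library totals also ended the calls of Srsf7 (0.0846) and Ncl (0.192), limma-voom that of Srsf7 (0.0850), and DESeq2 size factors and no low-count filter that of Ncl (0.0542 and 0.0562). Of 17 importin, dynein and retrograde signalling genes, 3 rose and none fell in edgeR's test (5 and 2 adjusted over the list alone, 5 and 0 with the replicate block, 5 and 1 with DESeq2, 3 and 0 with limma-voom). The list's camera adjusted p was 0.120. Fry, without a comparison with other genes, gave 0.0243, and the range over all alternatives reached an adjusted p of 0.547 with an estimated correlation. The 3 were Vim (vimentin), from 224 ± 32.3 to 376 ± 22.6 CPM, Stat3, and the dynein heavy chain gene Dync1h1 (1.20-fold), the last not without naive replicate 2 (adjusted p = 0.0506). Kpnb1, importin beta 1, had 90.5 ± 4.505 and 104.6 ± 5.93 CPM (adjusted p = 0.0611; 0.0448 with the replicate block, 0.0376 with DESeq2, range 0.0376 to 0.209 over all alternatives).

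**Figure D3:**
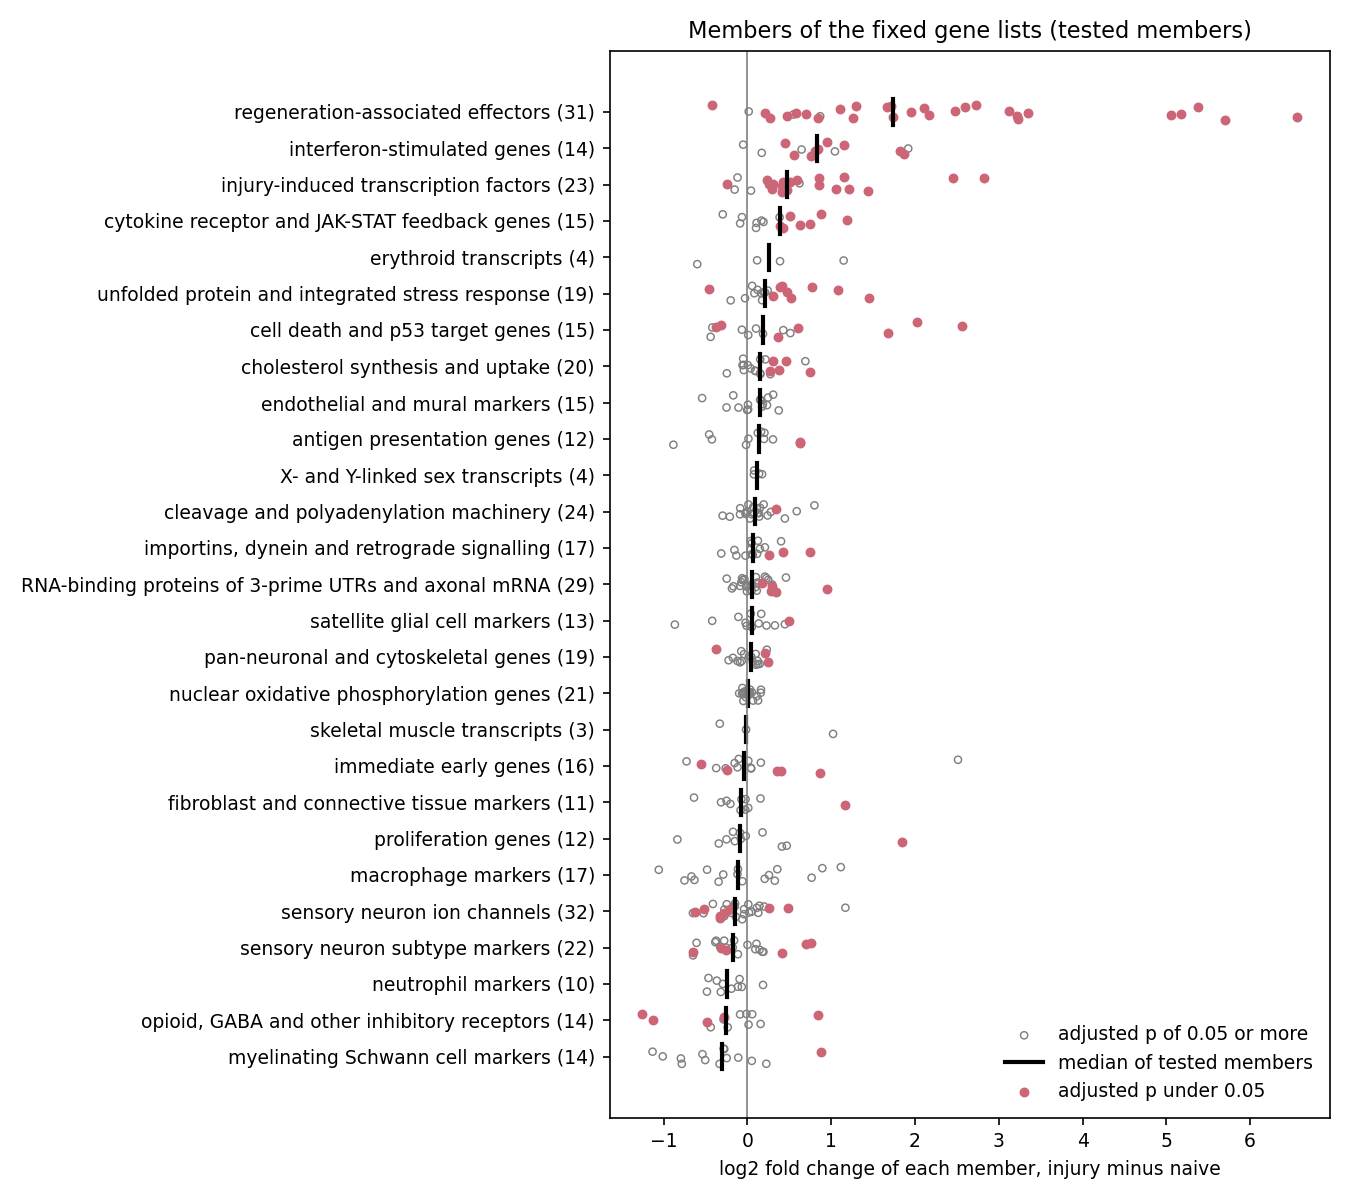
Log2 fold change, injury minus naive, of each tested member of the 27 tested lists. Filled points passed an adjusted p of 0.05 over all genes, open points did not, and vertical bars are list medians; the numbers of tested members stand in parentheses. Regeneration-associated effectors have the highest median, 1.74, and myelinating Schwann cell markers the lowest, -0.31, with 1 member called.

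In all, 6 of the 27 tested lists passed camera's threshold, all upward, and 7 with the replicate block. These lists are not all separate. Another list also holds 7 of the 23 transcription factors, 2 of the 19 stress response genes and 1 of the 15 JAK-STAT genes. With an estimated correlation 1 passed, the injury-induced transcription factors. With an estimated correlation and the replicate block no list passed, the lowest camera adjusted p being 0.396. Of the 35 divisions of the 8 libraries into 4 and 4, 17 gave at least 6 lists, the real division included, so the number of lists alone does not set the injury apart. Median, mean and test of a list differed in sign for the immediate early genes (median -0.05, mean 0.11, test upward), proliferation genes (median -0.08, mean 0.08, test upward), fibroblast markers (median -0.07, mean -0.03, test upward) and skeletal muscle transcripts (median -0.02, mean 0.22, test downward).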

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

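The tests of this part were chosen after the results were seen, except the search for single libraries far from their group. That search compared, on log2 CPM, the gap between an extreme library and its nearest neighbour with the range of the group and used Dixon's 95% critical value for 4 libraries. Of 212 groups of 4 examined, 8 passed, where chance at 1 in 20 gives 10.6. Injury replicate 1 was the extreme library in 4 of them. It was low for Sox11 (262 CPM against 374 to 399, ratio 0.847), Gal (78.9 against 192 to 218 CPM, 0.875) and Npy (9.87 against 26.9 to 30.05 CPM, 0.899), and high for Ddit4 (92.8 against 66.2 to 67.9 CPM, 0.927), a gene that fell after injury. Naive replicate 1 was low for Sqle (159 against 214 to 217 CPM, 0.959), naive replicate 2 low for Isl1 (113 against 122 to 124 CPM, 0.867), naive replicate 3 high for Usp18 (3.84 against 1.88 to 2.09 CPM, 0.857) and naive replicate 4 high for Tac1 (609 against 520 to 532 CPM, 0.847).

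Rises in injury replicate 1 were smaller beyond these genes as well: among 190 genes with a mean of at least 5 CPM that rose at least 2-fold in the fit without that library, its rise was a median of 0.609 of the mean rise in the other injury libraries (bootstrap over genes, 95% interval 0.563 to 0.654), against 0.943 to 1.22 when each of the other injury libraries was treated alike. Rises were taken from the mean of all naive libraries, not from the paired one. The interval covers the spread over genes, not that between libraries. Among 663 called falls with a mean of at least 5 CPM, the median for injury replicate 1 was 0.692. It was 0.785, 0.930 and 1.11 for injury replicates 3, 2 and 4, each over its own called falls. Falls of any size were taken, unlike the rises of at least 2-fold, so the medians of rises and falls cannot be set against each other. Lower depth is argued against, since its 22466009 counts (22.5 M) are the most of the 4 injury libraries. So is a naive library under an injury label, which would put the median near 0 where it was 0.609, with a lower bound over genes of 0.563. An admixture of RNA from uninjured ganglia may remain. It would scale all responses alike, and the ratio differed between gene lists (permutation p = 0.00126). It was 0.214 for 10 called interferon-stimulated genes, 0.533 for 29 effectors and 1.01 for 7 cell death genes. But the ratios of injury replicate 4 differed between lists as well (permutation p = 0.0041), so that uneven ratios do not decide the question. Both p-values come from shuffling list names over genes within 1 library, as if genes were independent. Genes of a list can move together (camera's estimated correlation was 0.468 for interferon-stimulated genes and 0.333 for effectors). These p-values therefore do not measure the spread between libraries. Injury replicate 1 also held 8 counts of Xist, an RNA of the inactive X chromosome, where the 7 others held 0. This leaves a small share of RNA from a female source open. A share large enough to bring the rises to 0.609 would lower transcripts of the Y chromosome in that library. Ddx3y, of the Y chromosome, was at 98.5 CPM there, against 88.9 to 96.4 CPM in the other injury libraries. Eif2s3y and Kdm5d, also Y-linked, were likewise highest there among the injury libraries, and Uty lay within the range of the others. These values argue against a female source as the cause of the smaller rises. The design names no group that could test a biological explanation, such as an earlier stage of the response.

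The division of libraries into injury and naive was compared with the 34 other divisions into 4 and 4. The real division called 1717 genes and the next highest 2, the one that exchanges naive replicate 1 with injury replicate 1; it called 1108 higher and 609 lower genes where no other division had more than 2 on either side, and 269 genes changed at least 2-fold against 1. For each of these counts 1 division of 35, the real one, reached the real value. That is the smallest share that 35 divisions allow. The other divisions mix injury and naive libraries, so the injury itself widens the spread within their groups and lowers their counts. These counts also overlap. Among the 7 other divisions that part all 4 pairs the highest count was also 2. With the pairs kept only 8 divisions remain, too few to give a share under 0.05. The real division thus stands apart, but the comparison cannot exclude chance. For the number of gene lists the real division does not stand apart: 17 of 35 divisions gave at least the real 6 lists, the highest 12, and among those that part all pairs the highest was 10. The 6 lists differed when taken singly. Only the real division reached the camera p of the transcription factors, the effectors, the stress response and the JAK-STAT genes. For interferon-stimulated genes 4 of 35 divisions gave a camera p as small, and for cholesterol genes 9. The limits of such shares given above hold here as well.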

How the results depend on the processing

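The fit without both libraries of number 1 was chosen after the data were seen; all other alternatives were planned. The number of changed genes stayed within 1.5 times of 1717 in every alternative run, from 1299 without injury replicate 4 to 2024 with the replicate block. The block gave 1245 higher and 779 lower genes, 282 changed at least 2-fold and 7 lists; it shared 1694 of the 1717 calls and lost 23. Leaving out 1 library gave 1299 to 1859 changed genes, 847 to 1156 genes higher after injury, 452 to 703 genes lower after injury, 242 to 328 changed at least 2-fold and 5 to 7 lists. Library totals in place of TMM gave 1001 genes lower after injury, where the share of higher calls was 47.0%. The TMM factors were 1.01 to 1.03 in the naive and 0.965 to 1.01 in the injury libraries. Leaving them out therefore lowers the log2 fold changes, with a median over all genes of -0.06 in place of -0.004. The balance of rises and falls thus depends on the scaling, and why the factors differ was not tested. Requiring a mean of at least 5 CPM left 175 genes changed at least 2-fold, as fewer genes were tested (10113). Camera with an estimated correlation passed 1 list, and fry, which does not compare a list with other genes, 8. Without both libraries of number 1, 1956 genes were called, 1519 of them among the 1717. Of 105 named genes 91 were called, and 72 of these kept call and direction in all 16 alternatives in which they could be tested; 19 were lost in at least 1 and 0 reversed. Of the genes not called, Ctss turned in sign with limma-voom (log2 fold change 0.0621) and without naive replicate 1 or 2 or injury replicate 3 or 4 (range with 1 library left out -0.396 to 0.126), and S100a8 without naive replicate 2 (0.0266, range -0.551 to 0.0266); the cause was not tested. The replicate block ended 2 calls (Gal and Npy) and added 7 (Fabp7, Lgi4, Pecam1, Papola, Kpnb1, Cox5a and Ndufa4), and among the lists it added the ion channels (but adjusted p = 0.551 with an estimated correlation and the block); with camera's preset correlation it changed no other call of a named gene or list. Among all list members it ended 4 calls and added 21. Depth limits what a count of 0 in a library can exclude, at best levels above 0.102 to 0.195 CPM before TMM scaling. Where a 0 comes from the counting, as it may for Kpna2, it excludes no level.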

Other observations

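The tests on interferon-stimulated genes and neutrophil markers in this part were chosen after the results were seen. Of 12 proliferation genes tested, only Cenpf, a centromere protein gene, was called, in both adjustments, rising from 2.67 ± 0.926 to 9.56 ± 1.68 CPM (edgeR adjusted p = 2.66e-05), while Mki67 had 0.921 ± 0.493 and 1.30 ± 0.353 CPM (adjusted p = 0.690; list camera adjusted p = 0.906). None of 21 nuclear oxidative phosphorylation genes passed edgeR's test in either adjustment, with log2 fold changes between -0.10 and 0.16 (camera adjusted p = 0.906); 2 had an unadjusted p under 0.05, DESeq2 called 2 higher and limma-voom 1. The replicate block called Cox5a and Ndufa4 higher (adjusted p = 0.0360 and 0.0482 with the block, 0.0509 and 0.0722 without). Both were called by DESeq2 (0.0336 and 0.0379), and Cox5a by limma-voom (0.0424) and without naive replicate 1 (0.0413), injury replicate 1 (0.00965) or both (0.00561). Over all alternatives the ranges were 0.00561 to 0.198 and 0.0379 to 0.253. Mitochondrially encoded genes were not found among the symbols of the table under the names used. None of 4 erythroid, 3 skeletal muscle and 4 sex-linked transcripts passed edgeR's test in either adjustment (camera adjusted p = 0.433, 0.922 and 0.597), with 0 at an unadjusted p under 0.05 and 0 called by DESeq2 or limma-voom, and no lymphocyte marker had enough counts to be tested. Ddx3y, of the Y chromosome, was at 79.4 to 98.5 CPM in all libraries.

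Of 14 tested interferon-stimulated genes 9 rose, while edgeR, DESeq2 and limma-voom called 0 of 17 macrophage markers, 3 of which had an unadjusted p under 0.05. The 14 genes summed to 365 ± 28.6 CPM in the naive and 522 ± 93.5 CPM in the injury group, a difference of 157 CPM. An exact permutation test, two-sided and without regard to the pairs, gave p = 0.0571. The injury library was the higher one in each same-numbered pair. The 17 macrophage markers differed by 1.73 CPM (33.4 ± 8.66 and 35.1 ± 7.15 CPM), so no rise near 157 CPM was seen in them. Ctss, the most abundant marker, had 5.99 ± 2.61 and 5.68 ± 2.45 CPM, and 0 of the 17 stand in another list. Macrophages entering the ganglion would bring their abundant transcripts along, but these markers were low in all libraries, and counts here can be lost. Cd14, Mrc1 and Cx3cr1, the 3 with an unadjusted p under 0.05, were higher after injury. The median log2 fold change of the 17 was -0.11, and camera's direction was downward. Of all 13639 tested genes 3352 had an unadjusted p under 0.05, a larger share than 3 of 17, so these 3 rises are no sign of entry. With markers this low, the sums cannot decide whether macrophages entered. A single library is argued against: the list's adjusted camera p was at most 0.000144 with any 1 library left out, while injury replicate 1, at 387 CPM, lay within the naive range, above 369 CPM in naive replicate 1. That holds for camera's preset correlation only; the list did not pass with an estimated correlation (adjusted p = 0.484). Chance division stays open for the list test, as 4 of 35 divisions gave a camera p as small, the smallest of the others being 4.24e-10. A response within neurons or resident glia may account for the higher genes, but these data, which hold no separated cells, do not test it.

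Neutrophil markers were abundant in some libraries of both groups and did not follow the injured side. Their sum was 555.3 CPM in naive replicate 2, 215 CPM of it S100a8, and 163 to 319 CPM in the injury libraries. This argues against an effect limited to the injured side as the cause of the variation. Both groups come from mice with a crushed nerve, so an effect of the injury on both sides was not tested. Among 5 relations with other marker lists over the 8 libraries, that with erythroid transcripts was closest (Pearson r = 0.916, permutation p = 0.00858, adjusted 0.0429; Spearman rho = 0.762, p = 0.0368, adjusted 0.184), the others lying between -0.0715 and 0.597. Without naive replicate 2 and injury replicate 4, the libraries farthest from the median, r was 0.731 (permutation p = 0.117), so the relation rests in part on them. Blood or marrow cells left on the ganglia may be the source, but the test cannot settle it: Hba-a1, Hba-a2 and Hbb-bt, which blood would bring in large amounts, have 0 counts in all libraries, as do Trpv1 and Kpna2, so that 0 may here come from the counting, and Hbb-bs had 0.101 to 2.41 CPM.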
